A study of Mus musculus with 16 samples.

How the data were processed

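Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 histone methylations in hematopoietic stem cells of C57BL/6 mice. Per the labels, the cells came from bone marrow and were sorted as SP-KSL-CD150+, a gate that combines dye efflux with surface markers and is used to enrich long-term stem cells. The mice were 4 months old (called young here) or 24 months old (called old). H3K4me3, which lies at active promoters, was measured in 2 young and 2 old libraries. H3K27me3, the mark of Polycomb repression, was measured in 3 young and 3 old libraries, and so was H3K36me3, which lies over transcribed gene bodies. Per the labels' protocols, chromatin was sonicated, precipitated with an antibody to each mark and made into libraries with the ThruPLEX kit. Replicate numbers run over the marks in the labels, 1 to 3 for H3K27me3, 4 to 6 for H3K36me3 and 7 to 8 for H3K4me3, and are used as names here. The labels call each sample a technical replicate of a numbered biological replicate. They do not say which samples came from the same animals, so p-values measure the spread between these samples, which may be partly technical. Sample titles also carry a number, between 16 and 21, that the labels do not explain. Where a number occurs at both ages for a mark, the values within it are given beside most pooled values.

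The deposited files were peak lists, 1 per library, so the authors called peaks in each sample. These lists do not show whether peaks were also called on pooled samples. Per the submitters' processing notes, CASAVA 1.4, SICER and MACS were used and coordinates are on the mouse build mm9. Versions of SICER and MACS, the aligner, thresholds, control libraries and read depth are not given in the sources used here. The layout of the deposited H3K27me3 lists was that of SICER islands, with bounds on a fixed grid of 200 bp, while the H3K4me3 and H3K36me3 lists had the layout of MACS peaks. Each list gave a score per peak, as the authors deposited it, with no statement of its unit. In the H3K4me3 and H3K36me3 lists no score was below 80 and none was above 3100, a ceiling reached by 47.7 to 59.7% of H3K4me3 peaks. Scores were used mainly to rank peaks within a list, and the percentile of a score is the share of peaks in its list with a lower score. The ratio of high to median score was also compared between the H3K27me3 lists, and raw scores are given for some named regions. With the unit unknown, these values may not be on the same scale in every list. Because read depth is unknown, no interval for counting error could be given, and the number of peaks and covered length of a list depend on depth and on the enrichment of the mark as well as on its extent in the cells.

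For every list the number of peaks, the length of the genome under peaks and the median peak width were computed. Old and young were compared on the log2 scale with an exact two-sided permutation test within each mark. The smallest p the design allows is 0.333 for 2 against 2 libraries and 0.1 for 3 against 3 or 2 against 3, so none of these tests could reach 0.05. Peaks of all libraries of a mark were then merged where they shared at least 1 bp or abutted, and a library was said to hold a merged region when at least 1 bp of it lay under a peak of that library. Counts of regions held by all libraries of an age and by none of the other were set beside the counts for every other set of the same libraries. The length covered in each merged region was tested with limma 3.58.1 in R 4.3.3, on log2(bp covered + 200), with a trend and empirical Bayes moderation, for regions covered in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Overlap between lists was expressed as the Jaccard index, shared over joint length, and as the ratio of shared length to the mean of 100 circular shifts of 1 list along each chromosome. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

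The limma step was tested on simulated data in which 200 regions were changed by known amounts within the spread of the real libraries. For the 17307 H3K4me3 regions it recovered 10 of 100 regions changed by 1 and 57 of 100 changed by 3 on the log2 scale, with 1 false call. For the 30998 H3K27me3 and the 45189 H3K36me3 regions it recovered 0 of 100 at either size, while with a small simulated spread it recovered 200 of 200 for both marks. Simulated lengths were cut at 0, so changes of 3 came out at a median of 2.17 for H3K27me3 and 2.29 for H3K36me3. At the simulated spread, drawn as normal, the test therefore had little power for single regions of these marks. Real regions can have no coverage in any library of an age, and the power for such regions was not measured.

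Gene annotation of mm9 was not used here. The annotation at hand is on GRCm38, and coordinates were not converted between builds, so regions are given by position and no gene is named. Merged regions took the place of genes in the tests, as planned for that case before the data were examined, and the planned comparisons of gene lists, of promoters and of gene bodies were not run. The regions named are up to 5 per mark and direction, those with the largest mean covered length among regions held by every library of an age and by none of the other, a rule also fixed before the data were examined. Other regions named, described as the longest, as found without a library or as touched by H3K27me3 in young libraries alone, were chosen after their values were seen. Alternatives tried were a stricter peak threshold, equal numbers of peaks per list, joining of peaks within 1000 bp, at least 50% of a region covered to count as held, a pseudocount of 1000 bp, no filter, centring of libraries, a replicate block, comparison within shared title numbers and leaving out each library in turn. The stricter threshold kept peaks that scored at or above the median of their own list, so the cutoff was not common to all lists. Measures of how the marks overlap each other, an equal number of regions per library, and all values without young H3K27me3 replicate 1 or young H3K36me3 replicate 4 beyond the planned leave-out were added after the data were seen.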

Results

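The 16 libraries profiled H3K4me3, H3K27me3 and H3K36me3 in purified stem cells at 4 and 24 months, to ask how these marks differ with age. The H3K4me3 lists held 16258 to 19923 peaks and covered 26.9 to 32.5 Mb. The H3K27me3 lists held 17752 to 47197 islands and covered 123 to 179 Mb. The H3K36me3 lists held 6399 to 84437 peaks and covered 5.9 to 138 Mb, and among the young libraries this mark varied most in both values. Lists of the same mark overlapped each other more than lists of different marks, apart from the libraries named below. H3K4me3 lists overlapped each other 68.1 to 78.8 times as much as circularly shifted lists, H3K27me3 lists 5.98 to 8.69 times without young replicate 1, and H3K36me3 lists 13.7 to 20.5 times without young replicate 4. H3K27me3 and H3K36me3 excluded each other, with an overlap of 0.0298 to 0.0787 times that of shifted lists in the same libraries. Without the same 2 libraries, H3K27me3 overlapped H3K4me3 1.25 to 2.36 times as much as shifted lists, and H3K36me3 overlapped H3K4me3 0.149 to 0.399 times as much.

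Young H3K27me3 replicate 1 and young H3K36me3 replicate 4, which share the title number 16, stood apart from the other libraries of their mark. Old H3K36me3 replicate 4 has that number too and did not stand apart. Its overlap with the H3K36me3 lists other than young replicate 4 was 14.5 to 20.5 times that of shifted lists. Islands of young H3K27me3 replicate 1 overlapped those of the other 5 H3K27me3 libraries only 0.567 to 0.781 times as much as shifted lists, and 83.0% of the merged regions it held were in no other list. Its overlap with H3K4me3 lists was 0.0547 to 0.0862 times that of shifted lists. It had 10 domains of at least 20 kb, against 366 to 1215 in the other 5. Young H3K36me3 replicate 4 had 6399 peaks over 5.9 Mb, and 60.7% of its regions were in no other list, though it overlapped the other H3K36me3 lists 7.39 to 15.8 times as much as shifted lists. The lists of the 2 libraries that stood apart overlapped each other 6.91 times as much as shifted lists. The leading values of both marks are given with and without these libraries.

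**Figure D1:**
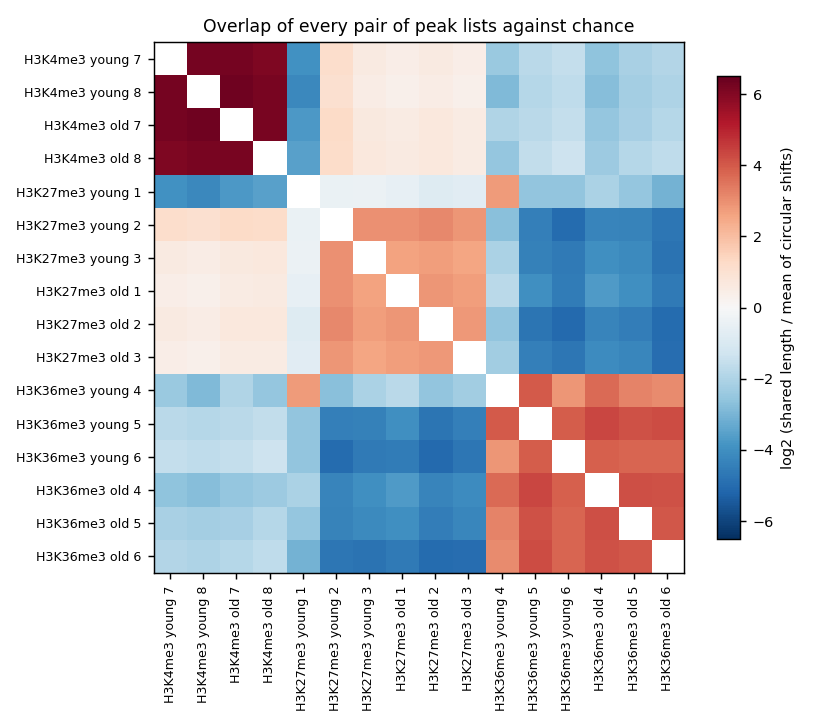
Overlap of every pair of the 16 peak lists, as log2 of the shared length over the mean of 100 circular shifts; red is more and blue less overlap than shifted lists, and both axes list the libraries by mark, age and replicate. The 3 marks form blocks, from which young H3K27me3 replicate 1 is absent, with 0.567 to 0.781 times the shifted overlap with its own mark.

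The H3K4me3 lists of both old libraries held more peaks, of lower median width, than those of both young libraries. The old lists held 19299 ± 882 peaks (SD, n = 2) and the young lists 16286 ± 39.6 (SD, n = 2), a log2 ratio of 0.24. Median peak width was 1399.5 ± 98.3 bp (SD, n = 2) in old and 1602 ± 105 bp (SD, n = 2) in young libraries, a log2 ratio of -0.19. Covered length was nearly the same, 29.8 ± 3.77 Mb in old and 28.2 ± 1.88 Mb in young libraries. By the exact permutation test p was 0.333 for the number of peaks, 0.667 for covered length and 0.333 for width, where 0.333 is the smallest p that 2 against 2 libraries allow. With the stricter threshold the lists held 9762.5 ± 282 peaks in old and 9659 ± 67.9 in young libraries, a log2 ratio of 0.02, and the log2 ratio of width was -0.04. This threshold, the median score of each list, was 3100 in both young lists and old replicate 7, but 2640 in old replicate 8. With equal numbers of peaks the log2 ratio of width was -0.03. Within title number 18, the only one at both ages, the log2 ratios were 0.20 for peaks, -0.12 for covered length and -0.33 for width.

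The core of the H3K4me3 landscape was shared between the ages. Of 20660 merged regions, 14489 (70.1%) were held by all 4 libraries, and the median log2 change of covered length in them was -0.01. Both old libraries were longer than both young in 12.6% of these shared regions and shorter in 16.2%, where chance gives 16.7% each. The longest H3K4me3 domains were held at both ages. The domain at chromosome 8, 97499884 to 97518766, was covered over 16806 ± 404.5 bp in young and 17299 ± 1606 bp in old libraries (SD, n = 2 each). That at chromosome 6, 52169644 to 52185438, was covered over 15647 ± 129 bp and 15430 ± 118 bp, and that at chromosome 11, 18906952 to 18922156, over 14732 ± 471 bp and 14800 ± 108 bp. The domain at chromosome 6, 88141902 to 88155121, was covered over 10862 ± 1153 bp in young and 12585 ± 607 bp in old libraries, and both old libraries (12155 and 13014 bp) lay above both young ones (10046 and 11677 bp). That at chromosome 19, 43680437 to 43691998, was covered over 11325 ± 126 bp and 11083 ± 33.2 bp, with both old libraries below both young ones.

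Regions held by a single age were mostly old. Both old and no young library held 792 H3K4me3 regions, and both young and no old library held 48, while the 4 pairs that mix the ages held 100 to 229. With the same number of regions kept per library the counts were 233 and 252. Regions of either single age were short, with a median length of 811 bp in the old-only and 870 bp in the young-only set. Regions in all 4 libraries had 2023 bp. The median score percentile within their own list was 15.0 for old-only and 7.87 for young-only regions, against 41.1 for the shared regions. Ties at the ceiling of 3100, held by 47.7 to 59.7% of the peaks of a list, keep every percentile well short of the top. The 41.1 of the shared regions can thus stand for a score at or near the ceiling. The highest percentile possible was lower in the young than in the old lists. The old-only regions lay a median of 27039 bp from the nearest shared region. Islands of at least 3 of the 5 H3K27me3 libraries other than young replicate 1 touched 245 of them (30.9%), against 13.4% of the shared regions, with a Fisher's exact odds ratio of 2.89 and p = 8.56e-35. Among shared regions matched on score the share touched was higher than in the old-only regions, with a mean of 43.5% over 10000 draws and 95% of draws between 40.2 and 47.0%. H3K36me3 peaks, counted in the same way without young replicate 4, touched 8 of them (1.01%), against 2.91% of the shared regions, with an odds ratio of 0.34 and p = 0.00057 by Fisher's exact test. These tests run across regions of the same libraries, which are not replicates.

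The old-only H3K4me3 region of the largest mean covered length had a high score. It lay on chromosome 9 at 92170215 to 92173103, was covered over 2796 ± 87.7 bp (SD, n = 2) in old and 0 bp in young libraries, and its score reached the ceiling of 3100 in both old lists. Next came chromosome 7 at 134228220 to 134231350 with 1976 ± 1634 bp, chromosome 18 at 78319300 to 78321206 with 1766 ± 4.2 bp, chromosome 10 at 79380774 to 79382606 with 1703 ± 184 bp and chromosome 8 at 125976033 to 125978467 with 1580.0 ± 1209 bp in old libraries. No H3K27me3 library of either age held an island over any of these 5 regions. The young-only regions of the largest mean covered length were at chromosome X, 166427539 to 166429484, with 1665 ± 398 bp in young libraries, and chromosome 3, 122938300 to 122939459, with 1002 ± 223 bp. They were followed by chromosome 18 at 62347972 to 62349313 with 943 ± 385 bp, chromosome X at 166424066 to 166425221 with 936 ± 311 bp and chromosome 11 at 86707048 to 86708308 with 929 ± 469.5 bp. Both chromosome X regions were also held by H3K36me3 peaks in 2 young and 0 old libraries. The lowest H3K4me3 score over the first of them was 91.9, and no score in the list of young replicate 8 was below 91.9.

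No single H3K4me3 region passed the test for changed coverage. Limma called 0 of 17307 regions at an adjusted p under 0.05, and the smallest adjusted p was 0.348. At an unadjusted p under 0.05 there were 1253 regions, of which 1046 had more coverage in old libraries. Leaving out 1 library at a time, limma called 15 to 83 regions, with the lone library of an age assumed to vary like the others. Nearly all of these had more coverage in old libraries, except without old replicate 8, where 3 of 15 had. Without young replicate 8 and without old replicate 8 the split by age gave 15 calls each, and other splits of the same 3 libraries gave up to 24 and 22. Without young replicate 7 and without old replicate 7 the split by age gave more calls than the other splits. With only 2 other splits in each of these fits, ranking first says little about age.

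**Figure D2:**
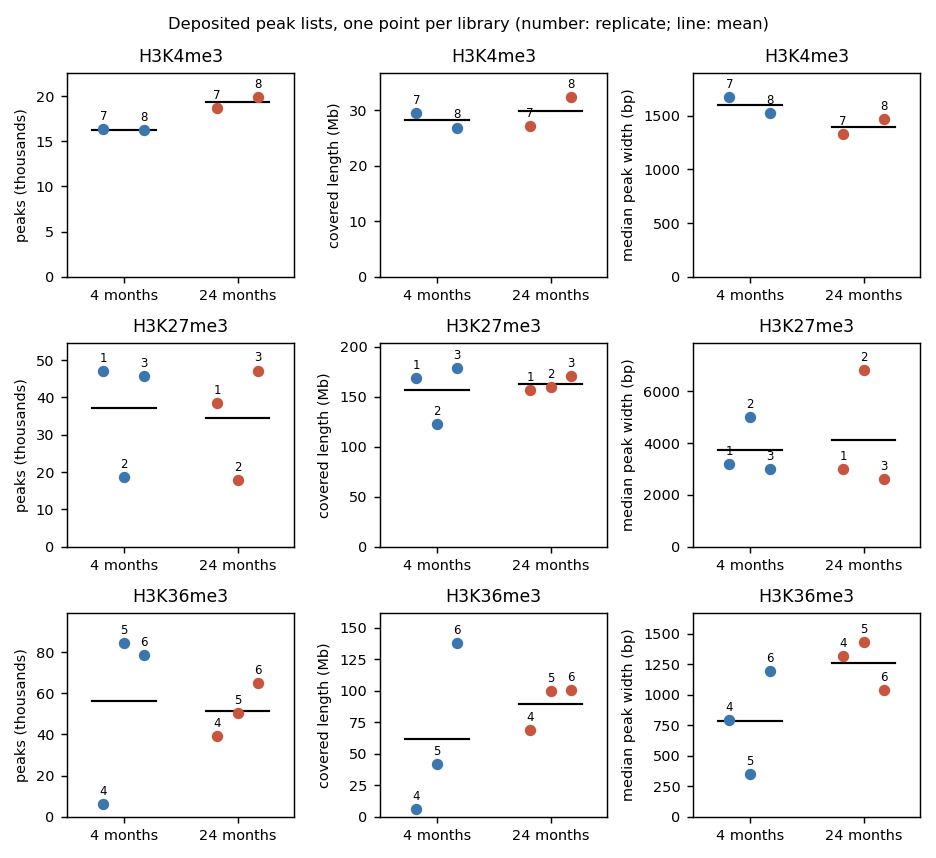
Number of peaks, covered length and median peak width of every deposited list, by mark and age; points are libraries labelled by replicate, lines are means, and axes start at 0. Both old H3K4me3 lists hold more peaks (18675 and 19923) than both young lists (16314 and 16258), while H3K27me3 and H3K36me3 libraries of the same age differ widely.

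H3K27me3 covered similar lengths at both ages. Old libraries covered 162 ± 7.25 Mb (SD, n = 3) and young libraries 157 ± 29.8 Mb (SD, n = 3), a log2 ratio of 0.07 with an exact permutation p of 0.9. The lists held 34519 ± 15143 islands in old and 37192 ± 15989 in young libraries, a log2 ratio of -0.11 with an exact p of 0.7. Median island width was 4133 ± 2318 bp in old and 3733 ± 1102 bp in young libraries, a log2 ratio of 0.05 with an exact p of 1.0, and the smallest p possible was 0.1 for each. Without young replicate 1 these log2 ratios were 0.13, 0.12 and -0.04. Within title number 18 they were 0.38 for covered length, -0.08 for islands and 0.44 for width, and within title number 20 they were -0.07, 0.04 and -0.21, so the sign differed between the numbers for all 3. Domains of at least 20 kb numbered 604 and 406 in young replicates 2 and 3, and 366, 1215 and 404 in the old libraries.

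The largest H3K27me3 domains were held at both ages. The longest merged domain lay on chromosome 15 at 102570201 to 102983000 and was covered over 376100.0 ± 4950 bp in young (SD, n = 2, without replicate 1) and 375000.0 ± 24764 bp in old libraries (SD, n = 3). The domain on chromosome 19 at 44655201 to 44992600 was covered over 301300.0 ± 424 bp and 311267 ± 15235 bp, and that on chromosome 5 at 112931801 to 113257200 over 256900.0 ± 12021 bp and 277067 ± 20843 bp. Across the 5989 regions held by the 5 libraries other than young replicate 1, the median log2 change of covered length was 0.05. All 3 old libraries were longer than both young in 14.5% of them and shorter in 10.3%, where chance gives 10% each.

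Few H3K27me3 regions separated the ages. All old and no young libraries held 835 of 109362 merged regions and all young and no old libraries held 178, while the set of young replicate 3 with old replicates 1 and 3 held 1532. Without young replicate 1 the counts were 918 old-only regions, held by 3 libraries, and 1242 young-only regions, held by 2, so these 2 counts are not alike. Sets of 2 libraries that mix the ages held 98 to 3042 regions, and sets of 3 that mix them held 67 to 1694. The old-only regions of the largest mean covered length were on chromosome 5 at 128374201 to 128406400 with 18067 ± 4277 bp in old libraries (SD, n = 3), at 26471001 to 26498600 with 17800.0 ± 9372 bp and at 131500401 to 131526000 with 14133 ± 8329 bp. The next were on chromosome 8 at 10433601 to 10457800 with 13600.0 ± 9302 bp and on chromosome 13 at 81362401 to 81380800 with 13200.0 ± 3995 bp. The young-only regions of the largest mean covered length, which by the rule include young replicate 1, were on chromosome 1 at 159913401 to 159929200 with 9533 ± 5686 bp, chromosome 11 at 49242201 to 49253800 with 8067 ± 924 bp and chromosome 9 at 74228601 to 74244600 with 7867 ± 5742 bp in young libraries (SD, n = 3). Those on chromosome 15 at 94530401 to 94545800 and on chromosome 1 at 144088001 to 144099800 had 7733 ± 4606 bp and 7533 ± 4500.4 bp. Without young replicate 1 the young-only region of the largest mean covered length, on chromosome 8 at 10172801 to 10188800, had 12900.0 ± 3818 bp (SD, n = 2). Limma called 0 of 30998 regions, with a smallest adjusted p of 0.552 and 1368 regions at an unadjusted p under 0.05, 1178 of them with more coverage in old libraries. The median log2 change over all tested regions was 0.48, and 0.01 after each library was centred. Without young replicate 1, 1378 of 2897 regions at an unadjusted p under 0.05 had more coverage in old libraries, limma called 0 regions, and the median log2 change was -0.001. Without old replicate 2, limma called 3264 regions, of which 3251 had no coverage in any young library.

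H3K27me3 touched fewer of the shared H3K4me3 regions in each old library than in young replicates 2 and 3, a difference that 5 libraries cannot carry past 0.05. Of the 14489 H3K4me3 regions held by all 4 H3K4me3 libraries, an H3K27me3 island touched 14.8% and 15.3% in young replicates 2 and 3, and 12.5%, 13.3% and 13.5% in old replicates 1, 2 and 3. The means were 15.0 ± 0.351% (SD, n = 2) and 13.1 ± 0.532% (SD, n = 3), with an exact permutation p of 0.1, the smallest that 2 against 3 libraries allow. Within title number 18 the shares were 14.8% in young and 13.3% in old, and within title number 20 they were 15.3% and 13.5%. Young replicate 1 touched only 1.48%, and with it the young mean was 10.5 ± 7.84% (SD, n = 3), which turns the direction of the difference, with an exact p of 1.0. Without young replicate 1, all 5 libraries touched 1421 regions (9.81%) and none touched 11776 (81.3%). Both young and no old libraries touched 155 regions, all old and no young libraries touched 24, and no other set of 2 or 3 of the 5 libraries touched more than 65. With equal numbers of islands per list these counts were 89, 23 and 47, and with the stricter threshold they were 64, 29 and 50. In the first setting, no other set of 2 libraries, the size of the young set, touched more than 24 regions. The other sets of 3, the size of the old set, touched 6 to 65.

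Of the 155 regions touched only in young libraries, 114 (73.6%) had no island of any old library within 5 kb, 41 had an island of at least 1 old library that near, and 2 had islands of all 3. For the other pairs of libraries, 62 of 160 regions (38.8%) had no island of the remaining 3 libraries within 5 kb. For the old-only set, 8 of 24 regions (33.3%) had no island of young replicates 2 and 3 that near. These shares were not tested. Young islands covered at least 50% of the region in both libraries in 109 cases. The regions had a median length of 2084 bp, against 2023 bp for all shared regions. By the mean of young replicates 2 and 3, the longest young islands in this set lay over a pair of neighbouring H3K4me3 regions on chromosome 16. These regions lay at 18625965 to 18627040 and at 18628989 to 18630551, with islands of 16000 and 12600 bp in young replicates 2 and 3. An old island lay within 5 kb of the first of these in 1 library. The next longest by this mean, on chromosome 10 at 126624957 to 126627544, had islands of 16800 and 6200 bp in young replicates 2 and 3. It had islands of all 3 old libraries within 5 kb.

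**Figure D3:**
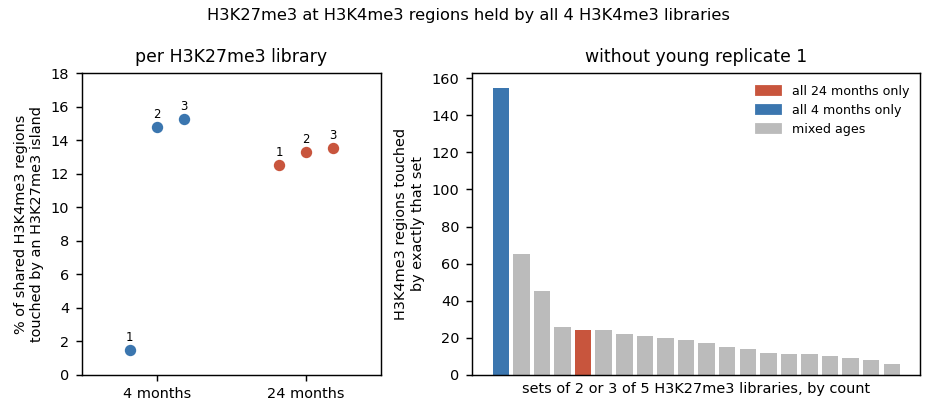
H3K27me3 at the 14489 H3K4me3 regions held by all 4 H3K4me3 libraries: left, percent of them touched by an island, per H3K27me3 library labelled by replicate; right, without young replicate 1, the number touched by exactly a given set of 2 or 3 of the 5 libraries, sets ordered by count. Young replicates 2 and 3 lie at 14.8 and 15.3%, above the 12.5 to 13.5% of the old libraries, and the set of young libraries alone has the highest bar at 155.

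Counted by consensus, more H3K4me3 regions lay under H3K27me3 in old than in young libraries. At 4 months 2035 of 14868 H3K4me3 regions in both libraries (13.7%) lay under a region held by at least 2 H3K27me3 libraries, and at 24 months 2394 of 16445 (14.6%). Of the young set, 1650 regions (81.1%) carried both marks in old libraries too, and 303 had H3K4me3 there but not both marks. Of the 744 old regions that did not carry both marks in young libraries, 198 already had H3K4me3 there. The young consensus rests in effect on replicates 2 and 3, since replicate 1 lay apart, while any 2 of 3 old libraries sufficed, which makes the old consensus easier to meet. The share was lower in old when single H3K27me3 libraries were compared. In title number 18 alone, with 1 library per mark and age, the counts were 2607 of 16314 (15.98%) in young and 2930 of 18675 (15.7%) in old. With the H3K27me3 libraries of title number 20 they were 2301 of 14868 (15.5%) in young and 2506 of 16445 (15.2%) in old. These counts give 1 value per age and were not tested. Per H3K4me3 library, 12.9 ± 0.29% of peaks in young and 14.0 ± 0.537% in old (SD, n = 2 each) touched an H3K27me3 region held by young replicates 2 and 3 or by all 3 old libraries, respectively. The exact permutation p was 0.333, the smallest possible.

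The H3K36me3 lists of old libraries had a higher mean peak width, within a large spread between the young libraries. Median peak width was 1265 ± 203 bp (SD, n = 3) in old and 782 ± 423 bp (SD, n = 3) in young libraries, a log2 ratio of 0.85 with an exact permutation p of 0.2. Covered length was 89.7 ± 18.3 Mb in old and 61.7 ± 68.2 Mb in young libraries, a log2 ratio of 1.45 with an exact p of 0.4. The lists held 51545 ± 12735 peaks in old and 56474 ± 43465 in young libraries, where the mean of log2 values gave a ratio of 0.53 with an exact p of 1.0. The smallest p possible was 0.1. Without young replicate 4 the log2 ratios were 0.94 for width, 0.22 for covered length and -0.69 for peaks. The log2 ratio of width was 0.36 without young replicate 5, whose median width was 354 bp, and 1.24 without young replicate 6. Within title number 16 the log2 ratios of width, covered length and peaks were 0.73, 3.54 and 2.62, and within title number 18 they were 1.56, 1.27 and -0.38.

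The largest sets of H3K36me3 regions mixed the ages. All old and no young libraries held 382 of 80861 merged regions and all young and no old libraries held 18, while the set of young replicate 6 with old replicates 5 and 6 held 2305. Without young replicate 4 the counts were 389 old-only regions, held by 3 libraries, and 2189 young-only regions, held by 2, so these 2 counts are not alike. Sets of 2 libraries that mix the ages held 164 to 3634 regions, and sets of 3 that mix them held 132 to 2364. The old-only regions of the largest mean covered length were on chromosome 10 at 107845656 to 107852906 with 5502 ± 1687 bp (SD, n = 3), chromosome 12 at 113259307 to 113264905 with 3962 ± 1941 bp and chromosome 15 at 6782441 to 6787606 with 3429 ± 1067 bp in old libraries. Those on chromosome 17 at 31607868 to 31612095 and chromosome 6 at 128727709 to 128730684 had 2654 ± 266.5 bp and 2582 ± 441 bp. The young-only regions of the largest mean covered length were on chromosome 9 at 113604362 to 113607146, chromosome 2 at 22824514 to 22826381, chromosome 16 at 84860533 to 84862519, chromosome 17 at 21589913 to 21591988 and chromosome 6 at 12015735 to 12017986. Their mean covered length was between 976 and 1119 bp in young libraries, young replicate 4 included. Without that replicate the young-only region of the largest mean covered length, on chromosome X at 166419199 to 166429333, had 7089 ± 4308 bp (SD, n = 2), above that of any old-only region.

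Limma called 0 of 45189 H3K36me3 regions, with a smallest adjusted p of 0.911. At an unadjusted p under 0.05 there were 257 regions, 252 of them with more coverage in old libraries. The median log2 change over all tested regions was 0.81, and -0.12 after centring, when 256 of 2661 regions at an unadjusted p under 0.05 had more coverage in old libraries and the smallest adjusted p was 0.0506. Without young replicate 4, 187 of 923 regions at an unadjusted p under 0.05 had more coverage in old libraries, limma called 0 regions, and the median log2 change was 0.06. Without young replicate 6, 11028 of 11030 such regions had more coverage in old libraries, with a median log2 change of 1.80. Without young replicate 5, 19 of 20 had, so single libraries moved these counts and their direction.

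A minor part of the H3K36me3 length lay near shared H3K4me3 regions at either age. Without young replicate 4, 13.2 ± 0.627% of the H3K36me3 length lay within 5 kb of a shared H3K4me3 region in young (SD, n = 2) and 11.5 ± 1.62% in old libraries (SD, n = 3), with an exact permutation p of 0.3. The share directly under H3K4me3 was 0.49 ± 0.054% in young and 0.349 ± 0.088% in old libraries, with an exact p of 0.2. It was 0.452 and 0.528% in young replicates 5 and 6 and 0.253, 0.368 and 0.427% in old replicates 4, 5 and 6. The smallest p possible was 0.1 for both shares. With young replicate 4 the share within 5 kb was 10.4 ± 4.95% in young libraries (SD, n = 3), below the old mean. Within title number 16 this share was 4.695% in young and 9.77% in old, and within title number 18 it was 13.7% and 13.0%. The share directly under H3K4me3 was 0.226% and 0.253% within title number 16, and 0.452% and 0.427% within title number 18.

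**Figure D4:**
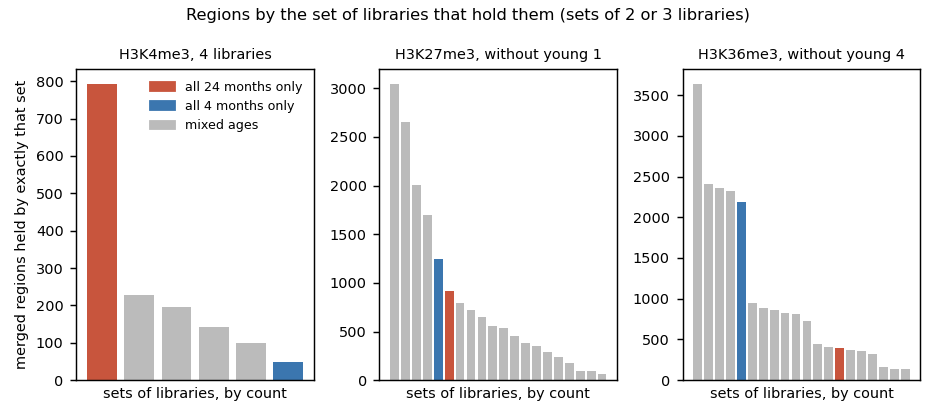
Number of merged regions held by exactly a given set of 2 or 3 libraries of a mark, sets ordered by count, for H3K4me3 with all 4 libraries and for H3K27me3 and H3K36me3 without the young library that stood apart. The old-only set has the highest H3K4me3 bar at 792, while in the other marks sets that mix the ages reach 3042 and 3634.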

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

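Equal numbers of regions per library, every alternative of the shares in which marks overlap, and, for the counts of H3K4me3 regions under H3K27me3, coverage of 50% and title number 20 were chosen after the data were seen; the other alternatives were fixed before the data were examined. The planned comparisons of gene lists, of promoters, of first and last parts of genes and of gene bodies, with their alternatives, were not run. Read depth is unknown, so its limit cannot be given. None of the single values per library could pass 0.05 at this size, so a kept direction says little about stability. They kept their direction in 23 of 24 alternatives that use all libraries, in 8 of 9 within title numbers and in 39 of 48 that leave out 1 library. The stricter threshold keeps about the same share of each H3K27me3 and H3K36me3 list. The direction of their peak number was thus nearly fixed in advance for that alternative. H3K4me3 covered length turned to a log2 ratio of -0.0095 with equal numbers of peaks and -0.12 within title number 18. Leaving out 1 library gave ranges that crossed 0 for H3K4me3 covered length (-0.0548 without old replicate 8 to 0.20), H3K27me3 number of peaks (-0.54 to 0.32), H3K27me3 covered length (-0.10 to 0.17), H3K27me3 median width (-0.38 without old replicate 2 to 0.31) and H3K36me3 number of peaks (-0.69 without young replicate 4 to 1.17). The range for H3K36me3 covered length was 0.22 without young replicate 4 to 2.4955 without young replicate 6, and for its median width 0.36 without young replicate 5 to 1.24. The cause was not tested. Old-only and young-only H3K4me3 regions numbered 162 and 142 with the stricter threshold, 224 and 272 with equal peaks, and 233 and 252 with equal regions; when 50% had to be covered there were 89 young-only regions, against 48 before. H3K27me3 gave 372 and 32 with the stricter threshold and 546 and 43 with equal regions, and 46 young-only regions with equal peaks and 42 with 50% covered. H3K36me3 gave 238 and 11 with the stricter threshold, 222 and 3 with equal peaks, 593 and 0 with 50% covered, 201 and 4 with equal regions, and 6 young-only regions with peaks joined. Some of these counts are higher and some lower than those of the settings first chosen, and the reasons were not tested. Leaving out 1 library removes a condition, and gave 1257 to 3165 old-only and 153 to 279 young-only H3K4me3 regions, 918 to 3623 and 204 to 1945 for H3K27me3, and 389 to 3164 and 26 to 2189 for H3K36me3. Limma called 0 regions in all 18 unblocked alternatives that use all libraries. Leaving out 1 library gave 15 to 83 H3K4me3 calls and 0 to 3264 H3K27me3 calls, and 0 H3K36me3 calls each time. All 3264 came without old replicate 2, where other splits of the same 5 libraries gave up to 2887. H3K4me3 regions under H3K27me3 numbered 326 at 4 months and 336 at 24 months with the stricter threshold. The old minus young difference in the share of H3K4me3 regions touched by H3K27me3 ranged from -1.93 percentage points without young replicate 1 to 4.97. That in the share of H3K36me3 near H3K4me3 was -0.13 points with equal peaks and ranged from -1.76 without young replicate 4 to 2.74 with 1 library left out.

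With the replicate number as a block, limma called 0 regions for every mark, and the paired log2 ratio of H3K4me3 peak number was 0.24, which a balanced design fixes at the unpaired value, so the paired ratios say nothing of stability. Across regions, deviations of same-numbered samples correlated at 0.1, 0.143 and 0.021 for H3K27me3, at 0.06, -0.031 and 0.033 for H3K36me3 and at 0.005 for H3K4me3. Not every sample correlated best with its own number, and not all H3K27me3 or H3K36me3 pairs passed 0.1, so the replicate numbers were not taken to pair the samples. Samples of the same title number correlated at 0.143 and 0.021 for H3K27me3, at 0.06 and 0.043 for H3K36me3 and at 0.005 for H3K4me3, and the labels do not say what that number marks.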

Other observations

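The tests on young H3K27me3 replicate 1, the counts without it or without young H3K36me3 replicate 4, and the choice of the regions below were made after the values were seen. A stretch of chromosome X held 2 marks in young libraries alone, though not in young H3K36me3 replicate 4. Without young H3K36me3 replicate 4, the young-only H3K36me3 region of the largest mean covered length lay at 166419199 to 166429333, with 7089 ± 4308 bp in young libraries (SD, n = 2) and 0 bp in all 3 old ones. It overlaps the young-only H3K4me3 regions at 166424066 to 166425221 and 166427539 to 166429484. The lowest young H3K4me3 score was 256.4 over the first and 91.9 over the second. No score in the list of young H3K4me3 replicate 8 was below 91.9. The next young-only H3K36me3 regions in this comparison were on chromosome 9 at 20709928 to 20718105 with 6214 ± 2778 bp, and on chromosome 5 at 147067935 to 147075269 with 5607 ± 2444 bp. Young-only H3K27me3 regions without replicate 1 included a pair of neighbours on chromosome 8, at 10132001 to 10145200 with 11800.0 ± 283 bp and at 10172801 to 10188800 with 12900.0 ± 3818 bp (SD, n = 2). An old-only H3K27me3 region lay nearby at 10433601 to 10457800, so this part of chromosome 8 held domains of either age.

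The first pattern is the excess of old-only over young-only H3K4me3 regions, 792 against 48. Longer old lists are a candidate explanation: with the same number of regions kept per library the ratio of old-only to young-only regions was 0.925. Weak signal near the calling threshold is another that the data leave open, since the median score percentile of the old-only regions was 15.0. For the young-only regions it was 7.87, so a low percentile is not particular to the old-only set. Ties at the ceiling score limit these percentiles, by different amounts in the young and old lists. Placement of new H3K4me3 at Polycomb domains is neither shown nor excluded. H3K27me3 touched 30.9% of old-only regions, above the 13.4% of all shared regions but below the 43.5% (40.2 to 47.0%) of shared regions matched on score. An excess beyond that of regions of like score was therefore not seen. The matching was on score alone, and old-only regions were shorter, with a median of 811 bp against 2023 bp for all shared regions. An effect of age on weak H3K4me3 sites stays open and may act through either of the first explanations, which these lists cannot separate from greater depth or enrichment of the old libraries.

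The second pattern is the position of young H3K27me3 replicate 1 apart from the other 5 libraries. A swap of labels with young H3K36me3 replicate 4 is argued against, since its islands overlapped the other 5 H3K36me3 lists by a median of only 0.169 times the shifted overlap. Another gap setting of the caller is argued against too, since the smallest gap was 800 bp in all 6 lists. Low enrichment of the mark remains a candidate explanation: its 99th percentile of score was 3.29 times its median, against 11.5 to 14.3 times in the other 5 libraries. Whether low enrichment would also bring overlap below that of shifted lists was not tested. That overlap was 0.567 to 0.781 times with its own mark and 0.0547 to 0.0862 times with H3K4me3. No biological explanation was tested, as its labels are those of the other young libraries.

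The third pattern is the lower median width of H3K4me3 peaks in old libraries, a log2 ratio of -0.19. In place of the smallest peak size, the median width of a small share of lowest-scoring peaks in each list was taken off every width. These sizes were 793 and 654 bp in young and 467 and 592 bp in old libraries. The narrowest peaks had 299 and 301 bp in young and 176 and 263 bp in old libraries. The median widths left were 883 and 873 bp in young and 863 and 877 bp in old libraries, a log2 ratio of -0.0132. The ratio stayed below 0, by less than the spread between libraries. That the smaller minimum peak size of the old lists explains the lower median width is therefore neither excluded nor shown. With equal numbers of peaks the log2 ratio was -0.03, and over the 14489 shared regions the median log2 change of covered length was -0.01, which argues against narrower marks at shared sites as the whole of the pattern. The sizes taken off, though not the corrected ratio, had been seen before this test was chosen.

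The counts of regions with changed coverage were 0 for H3K27me3 and 0 for H3K36me3, and the highest of the other splits of the 6 libraries was 0 for each, so all 10 of 10 splits gave as many. With 10 splits the share cannot go below 0.05, which is all that can be said of it.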
